A study of Rattus norvegicus with 8 samples.

How the data were processed

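The study measured gene expression in large against small retinal ganglion cells of the rat. Per the labels and the series text, ganglion cells carried a retrograde fluorescent tracer, were sorted by flow cytometry into a large and a small fraction with a transcription inhibitor present, and their RNA was amplified in 2 rounds, coupled to Cy5 or Cy3 and hybridised to 2-colour Agilent rat oligonucleotide arrays. The series holds 8 arrays, named here by the number in their title (39, 40, 41, 42, 43, 69, 70 and 71). Every array compares the same 2 kinds of RNA, so the arrays form 1 group and the comparison is the mean ratio against 0.

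The values used are those of the authors' deposited value table, with 41048 probes on each of 8 arrays. The scanner software, background correction and normalization are not given in the sources used here, and no scanner intensities were analysed. The unit was worked out from the deposited values, which are a log2 ratio of the 2 channels. On each array the values lie on a grid of 3 decimals shifted by 1 constant. Distances between the commonest value and the next commonest ones were compared with logarithms of ratios of small whole numbers. Of 88 such distances, 67 lay on a log2 of such a ratio within rounding, against 22 for log10 and 6 for the natural logarithm. The median of each array was 0.03, -0.08, -0.01, 0.03, 0.00, 0.00, 0.01 and 0.00 in the order above, so the arrays were centred close to 0. The table holds 73 values of a size above 15, which is the end of the ratio scale, 574 values of exactly 0, and 30 missing values.

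The direction of the ratio stays unknown. The labels give large cells as Cy5 in channel 1 and small cells as Cy3 in channel 2 on all 8 arrays, while the series text speaks of a dye swap. No label or header says which channel is the numerator, or whether swapped arrays had been turned. Values are therefore given as lying on the positive or the negative side. If the ratio runs channel 1 over channel 2 as listed, the positive side means higher in large cells.

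The labels say that each biological replicate had 2 technical subreplicates, without saying which arrays belong together. The 8 arrays therefore entered the test singly, as set before the data were examined. P-values over 8 arrays treat them as independent, which makes them too small where technical subreplicates share a biological replicate. The difference between the sets of arrays described in the report stays in the residual and works the other way.

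Probes were named through a probe table of the platform, updated by gene identifier through the RefSeq gene table of assembly GRCr8, which was used for names only. Of the 41048 probes, 23374 had 1 gene symbol, 48 had several and 17626 had none. The identifier of 23327 of the probes with 1 symbol was found in the RefSeq table, and 1 symbol was updated. Probes with 1 symbol gave 14802 genes, of which 9183 had 1 probe and 5619 had several. The mean of a gene's probes was taken on each array, and a gene needed a value on at least 6 arrays. No coordinates are printed, because the files name no genome build.

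The test was an intercept model in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with the Benjamini-Hochberg adjustment and an adjusted p under 0.05. Gene lists were tested with camera, 2-sided, at its preset inter-gene correlation of 0.01, over 37 lists fixed before the data were examined, with at least 3 measured members each. Of these lists, 14 hold markers of retinal and other cell types and 23 hold functional groups. A further 10 lists were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

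The genes named in the text follow a rule set before the data were examined. It takes the 12 highest and 12 lowest mean ratios among called genes with the same sign on every array and a gene symbol that is not a provisional or clone name. It adds the 3 called members of each list with the largest mean ratio in size, or the 2 largest as values only where a list had no called member. Nefl, Nefm, Nefh, Pou4f1, Pou4f2, Thy1, Rbpms, Sncg and Slc17a6 are named always, and Pou4f1 had no probe with 1 symbol.

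The fit was tested on simulated data built from the real spread of 14800 genes and the real difference between the sets of arrays described in the report, with independent arrays. Of 100 genes with a log2 ratio of 0.5 it recovered 61%, and of 100 genes with a log2 ratio of 1 it recovered 93%, with 2 false calls. With the set of arrays as a covariate the shares were 83% and 94%, with 9 false calls. Of 20 simulated lists shifted by 0.3 all 20 were called, and of 20 unchanged lists 0 were called. The simulated genes were independent of one another, so this does not test camera on lists with correlated members. In the real data the estimated correlation was 0.16 for rod markers and 0.55 for microglia markers.

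Alternatives fixed before the data were examined were median centring, scaling of the arrays, single probes, the most variable probe, other limits on missing values, array weights, a 2-fold limit, averages over drawn pairings of arrays, the run of title numbers as a covariate or alone, an exact sign-flip test, each array left out, and for lists an estimated correlation and fry. Chosen after seeing the data were the set of arrays as a covariate or alone, values at the end of the scale and exact 0 values as missing, arrays 39 and 40 left out, pairings across the sets, and arrays of neighbouring title numbers averaged or taken as a random block. Neighbouring means next in the order of title numbers: 39 with 40, 41 with 42, 43 with 69, and 70 with 71. Of these, 43 and 69 are not consecutive numbers and belong to different runs of titles. The number of arrays limits the precision of every value.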

Results

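Expression in large and small retinal ganglion cells, the neurons that carry the output of the retina to the brain, was compared on 8 arrays that each set RNA of sorted large cells against RNA of sorted small cells. The measurement is a log2 ratio per probe, summarised to 14802 named genes. The comparison asks which transcripts differ between ganglion cells of different body size. Values are means over arrays with their standard deviation, and n = 8 arrays unless another number is given. The direction of the ratio is not stated in the labels, so genes are described by the side of 0 on which they lie. If the ratio runs from the large-cell channel over the small-cell channel, as the labels list them, the positive side means higher in large cells.

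The 8 arrays fell into sets of 4. Arrays 39, 41, 43 and 70 (set 1) correlated positively with one another over all probes, as did arrays 40, 42, 69 and 71 (set 2), with Pearson correlations from 0.16 to 0.68 over these 12 pairs. Between the sets, 15 of 16 pairs correlated negatively, from -0.29 to -0.03, and arrays 41 and 42 at 0.16. The lowest Spearman correlation between the sets was -0.41. limma called 4970 genes on the difference between the sets in a model with the mean and the difference, and 4158 genes on the mean when the signs of 1 set were turned. A Pearson correlation under -0.3, the limit set beforehand for giving each value with its sign turned too, was not reached. The mean over the 8 arrays weights both sets equally, and all values below refer to it. They measure large against small cells only if any swapped arrays had been turned. Otherwise that contrast would lie on the difference between the sets and would cancel in the mean.

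**Figure D1:**
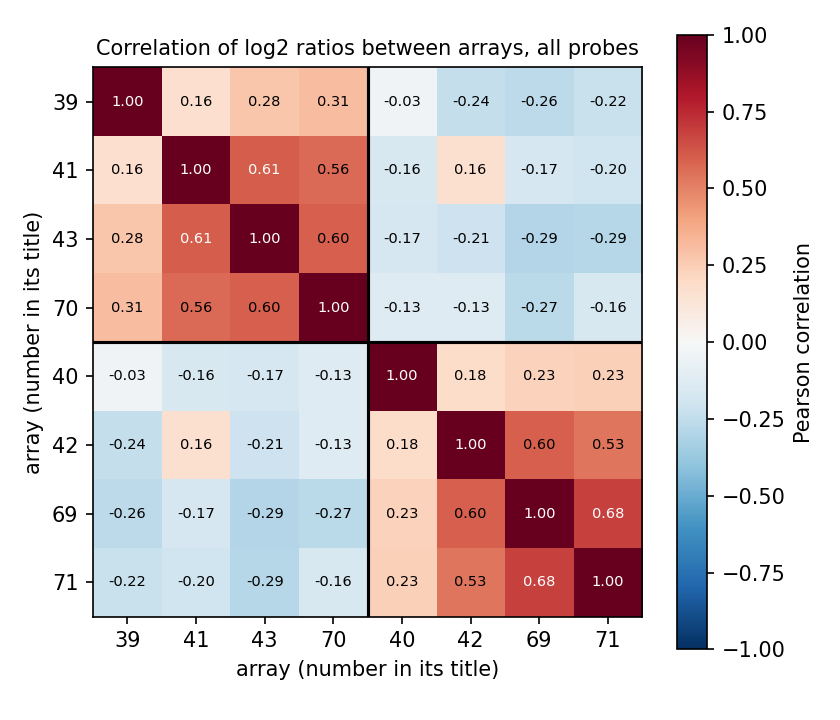
Pearson correlation of log2 ratios over all probes between the 8 arrays, with colour from -1 to 1 and both axes giving the number in the array's title. Arrays 39, 41, 43 and 70 correlate positively with one another, as do 40, 42, 69 and 71, while pairs across the dividing lines lie between -0.29 and 0.16.

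Of 14802 genes, 314 were called by limma, 233 on the negative side and 81 on the positive side. The changes were small. The median size was 0.49 on the log2 scale (1.41-fold), 94 genes reached 1.5-fold and 7 reached 2-fold. The same sign was seen on every array for 288 of the 314. The labels speak of 2 technical subreplicates per biological replicate, and counting these as independent makes p-values too small. The difference between the sets, which this fit leaves in the residual, makes them larger. With the set as a covariate the median standard error fell from 0.0965 to 0.0677. The 2 effects work against each other, so the p-values over 8 arrays are not reliable in either direction. Arrays of neighbouring title numbers were then averaged (39 with 40, 41 with 42, 43 with 69, 70 with 71). The labels do not give this pairing, it was chosen after seeing the data, and 43 and 69 are not consecutive numbers. From the 4 averages limma called 0 genes. At an unadjusted p under 0.05 there were 1920, against 1934 over the 8 arrays, and the lowest adjusted p was 0.0945. At an adjusted p under 0.1 the averages gave 156 genes, 125 of them among the 314. Single arrays also moved the count. It was 304 without array 39, 277 without 40, 190 without 41, 181 without 42, 148 without 43, 200 without 69, 118 without 70 and 163 without 71.

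The lowest mean ratio was that of Slc9b2, a sodium-proton exchanger, at -1.17 ± 0.34 (2.26-fold, limma adjusted p = 0.00197). Next came Tac1, the precursor of substance P, at -1.11 ± 0.28, the sodium channel gene Scn7a at -1.10 ± 0.49, and Nppc, which encodes C-type natriuretic peptide, at -1.09 ± 0.38. Below these in size followed Cntn2, an axonal adhesion molecule, at -0.96 ± 0.41, Npdc1 at -0.95 ± 0.43, the glucose transporter gene Slc2a6 at -0.95 ± 0.39, Evc2 at -0.94 ± 0.51 and Nell1 at -0.88 ± 0.39. Mex3c lay at -0.88 ± 0.54 as the mean of 11 probes on both sides of 0, whose single means ran from -0.98 to 0.11. This mean results when all probes but the highest share the lowest value, so it is not agreement of 11 separate measurements. With neighbouring arrays as a random block and set as a covariate, Mex3c lost its call (limma adjusted p = 0.117). All 10 of these genes were negative on 8 of 8 arrays.

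Voltage-gated sodium and potassium channels shifted to the negative side as a list (mean -0.24 ± 0.16 over 29 members, negative on 7 of 8 arrays, camera adjusted p = 0.000136), with an adjusted p = 0.109 with an estimated correlation. The 5 called members were all sodium channel subunits. Scn9a lay at -0.91 ± 0.49, Scn3a at -0.89 ± 0.47 and Scn3b at -0.71 ± 0.17, each negative on 8 of 8 arrays, and the 2 others were Scn2b at -0.68 ± 0.36 and Scn2a at -0.57 ± 0.29. The 3 probes of Scn2a had means from -0.87 to -0.07, and the 2 of Scn9a lay at -1.33 and -0.49. No potassium channel of the list passed the test over all genes. Outside the list, chosen after their values were seen, Kcnj5 at -0.58 ± 0.17 and Kcnt1 at -0.56 ± 0.25 did. Adjusted over the list alone, 8 members were called, all on the negative side.

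Cholesterol synthesis enzymes lay on the negative side on 8 of 8 arrays (mean -0.28 ± 0.14 over 18 members, camera adjusted p = 9.62e-07), and kept the call with an estimated correlation (adjusted p = 0.0448), but not with the set of arrays as a covariate besides (adjusted p = 0.223). The called members were 3, or 5 adjusted over the list alone. They were Tm7sf2, a sterol reductase, at -0.72 ± 0.40, Dhcr7, which makes the last step to cholesterol, at -0.64 ± 0.19, and Msmo1 at -0.58 ± 0.25. Of the 18 members, 16 had a negative mean.

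Axon guidance ligands and receptors shifted to the negative side (camera adjusted p = 0.000252 over 46 members, and adjusted p = 0.0448 with an estimated correlation, but 0.223 with the set of arrays as a covariate besides). Their mean was -0.12 ± 0.17 as deposited and -0.16 ± 0.08, negative on 8 of 8 arrays, without values at the end of the ratio scale, since Epha3 stood at 17.05 on array 39. The 5 called members were Cntn2, the ephrin receptor Ephb1 at -0.67 ± 0.27, the adhesion molecule L1cam at -0.61 ± 0.25, Epha5 at -0.58 ± 0.33 and Epha4 at -0.44 ± 0.15. Adjusted over the list alone there were 8, all negative. Neurotrophic factors and their receptors were called on the same side (mean -0.12 ± 0.09 over 22 members, camera adjusted p = 0.0319). The call was lost with an estimated correlation (adjusted p = 0.191), with the set of arrays as a covariate (adjusted p = 0.09) and over the 4 averages of neighbouring arrays (adjusted p = 0.0959). Their called member was Ret, the receptor for ligands of the GDNF family, at -0.37 ± 0.14 over 5 probes with means from -0.96 to 0.01, and adjusted over the list alone there were 4.

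Synaptic vesicle and release proteins had a mean of -0.09 ± 0.05 over 37 members and were negative on 8 of 8 arrays (camera adjusted p = 0.0127). The call was lost with an estimated correlation (adjusted p = 0.0813). The called members were Slc17a6, the vesicular glutamate transporter of ganglion cells, at -0.64 ± 0.38, Syngr3 at -0.58 ± 0.07 and the synaptotagmin gene Syt5 at -0.42 ± 0.23. Adjusted over the list alone, 11 members were negative and 4 positive. Cytosolic ribosomal proteins were called with a mean of -0.07 ± 0.20 over 68 members (camera adjusted p = 0.0296, and adjusted p = 0.688 with an estimated correlation). They were negative on only 5 of 8 arrays, with a mean of 0.07 in set 1 and -0.20 in set 2. Called members were 0 over all genes and 0 adjusted over the list alone. The 2 largest in size were Rpl3 at 0.36 ± 0.70 and Rpl29 at -0.31 ± 0.40.

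The positive side held genes of photoreceptors and immediate early genes. Egr2, a transcription factor of the immediate early class, had the highest mean ratio (1.54 ± 0.84, 2.92-fold, limma adjusted p = 0.0141). It was followed by Gpsm2, a regulator of spindle orientation, at 1.08 ± 0.54, and Prom1, which photoreceptors need to build their outer segment discs, at 1.07 ± 0.20. Further genes were Zfp36l1, which promotes decay of messenger RNA, at 0.77 ± 0.50, the inducible heat shock protein gene Hspa1a at 0.76 ± 0.33, Dennd2c at 0.74 ± 0.16, the photoreceptor gene Tulp1 at 0.72 ± 0.42, Tlcd3b at 0.70 ± 0.47 and Egr1 at 0.68 ± 0.40. The photoreceptor phosphatase gene Ppef2 lay at 0.67 ± 0.28 and the rod sodium-calcium exchanger gene Slc24a1 at 0.66 ± 0.21. Nfkbiz lay at 0.75 ± 0.35 as the mean of 2 probes at 0.05 and 1.45. All 12 of these genes were positive on 8 of 8 arrays. Not every called photoreceptor gene lay on this side. Outside the naming rule and picked after its value was seen, Rgs9 was called at -0.58 ± 0.28, negative on 8 of 8 arrays.

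**Figure D2:**
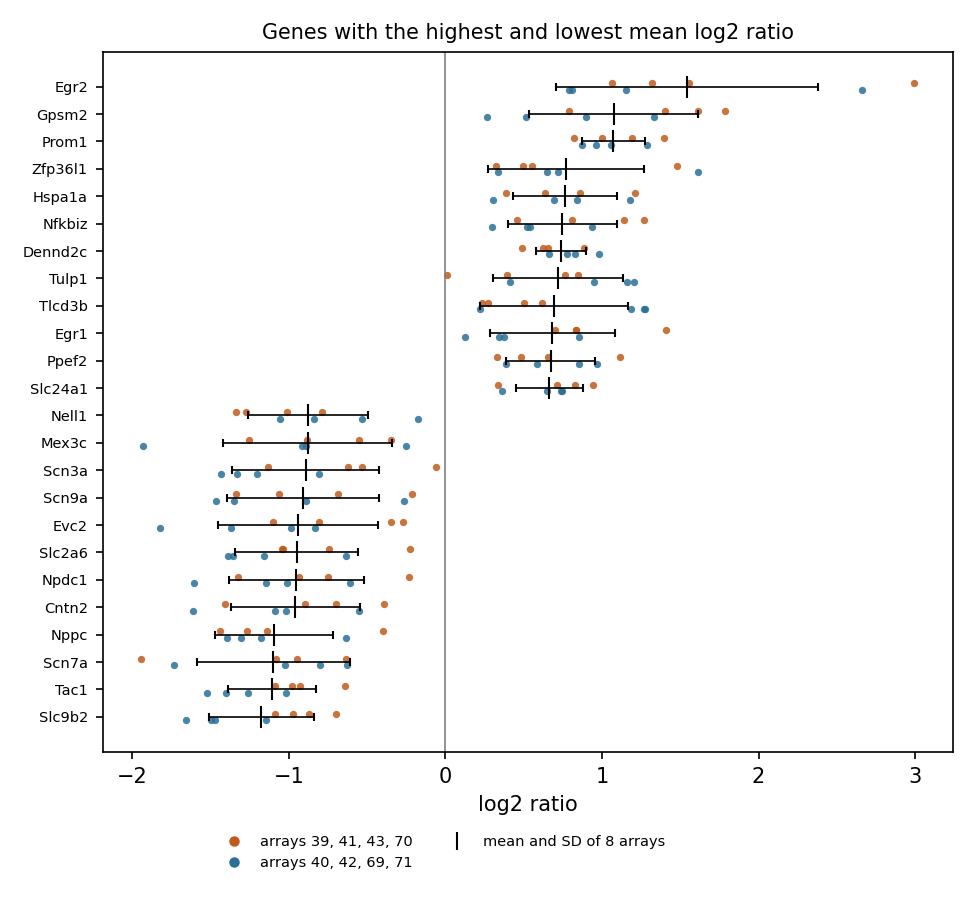
Log2 ratio (horizontal axis) of the 12 genes with the highest and the 12 with the lowest mean ratio among called genes with 1 sign on every array. Points are the 8 arrays, coloured by set, and black bars are the mean and SD; Egr2 is highest at 1.54 and Slc9b2 lowest at -1.17.

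Markers of cell types moved apart. Rod markers lay on the positive side on 8 of 8 arrays (mean 0.30 ± 0.23 over 17 members, camera adjusted p = 7.43e-07), and the call was lost with an estimated correlation (adjusted p = 0.0942). The called member was Rp1, a protein of the rod outer segment, at 0.83 ± 0.57, positive on 7 of 8 arrays, and 9 were called adjusted over the list alone. Cone markers had a mean of 0.22 ± 0.09 over 9 members, positive on 8 of 8 arrays (camera adjusted p = 5.65e-05), and were called with an estimated correlation too (adjusted p = 0.0448), but not with the set of arrays as a covariate besides (adjusted p = 0.223). Gnat2, the cone transducin, was called at 0.54 ± 0.21, and 6 members adjusted over the list alone. Amacrine cell markers had a mean of 0.11 ± 0.09 over 16 members (camera adjusted p = 0.0215, and adjusted p = 0.198 with an estimated correlation), with 0 called members, 1 adjusted over the list alone, and the largest values for Gad2 at 0.51 ± 0.41 and Slc17a8 at 0.43 ± 0.66.

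Ganglion cell markers lay on the negative side on 8 of 8 arrays (mean -0.17 ± 0.09 over 21 members, camera adjusted p = 0.000703, and adjusted p = 0.0745 with an estimated correlation). Slc17a6 and Thy1, a surface protein used to isolate ganglion cells, were called, the latter at -0.30 ± 0.11, and 4 members were called adjusted over the list alone. The other ganglion cell genes fixed for naming did not pass the test. The neurofilament genes lay at -0.33 ± 0.42 (Nefl), -0.16 ± 0.47 (Nefm) and -0.24 ± 0.39 (Nefh), Sncg at -0.09 ± 0.34, Pou4f2 at -0.01 ± 0.40 and Rbpms at 0.05 ± 0.46. Markers of large (alpha) and melanopsin ganglion cells were called on the negative side (camera adjusted p = 0.0407 over 18 members). The call was lost with an estimated correlation (adjusted p = 0.159) and with the set of arrays as a covariate (adjusted p = 0.0568). Their mean was -0.20 ± 0.39 as deposited and -0.09 ± 0.10 without values at the end of the scale, because Il1rapl2 stood at -16.94 on array 40. The only called member was Cartpt, a neuropeptide precursor, at -0.80 ± 0.39, negative on 7 of 8 arrays, and the other 17 were not called. Adjusted over the list alone, 2 were called.

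Microglia and macrophage markers were called on the positive side (mean 0.20 over 22 members, camera adjusted p = 0.000695), with 0 called members, also adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.46) and without arrays 39 and 40 (adjusted p = 0.609). The list mean differed between arrays more than that of any other of the 37 lists, also without values at the end of the scale. It was 0.84 and 0.74 on arrays 39 and 40, -0.28 and -0.36 on arrays 41 and 42, and 0.16, 0.13, 0.21 and 0.19 on arrays 43, 69, 70 and 71, with an SD of 0.42. The largest members were Itgam at 0.74 ± 0.80 and P2ry12 at 0.65 ± 0.60.

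Immediate early and injury response genes were positive on 8 of 8 arrays (mean 0.20 ± 0.19 over 31 members, camera adjusted p = 0.00016), but not called with an estimated correlation (adjusted p = 0.232) or without arrays 39 and 40 (adjusted p = 0.0915). Called were Egr2, Egr1 and Jun, the last at 0.48 ± 0.31, and 7 members adjusted over the list alone. The list mean was 0.59 on array 39 and 0.38 on array 40 (0.66 without values at the end of the scale), the arrays that were also highest for microglia markers, and from 0.08 to 0.16 on the other 6. Heat shock proteins and chaperones had a mean of 0.10 ± 0.15 over 33 members, positive on 5 of 8 arrays (camera adjusted p = 0.0127, and adjusted p = 0.392 with an estimated correlation). Hspa1a was called, and adjusted over the list alone 3 were positive and 1 negative.

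**Figure D3:**
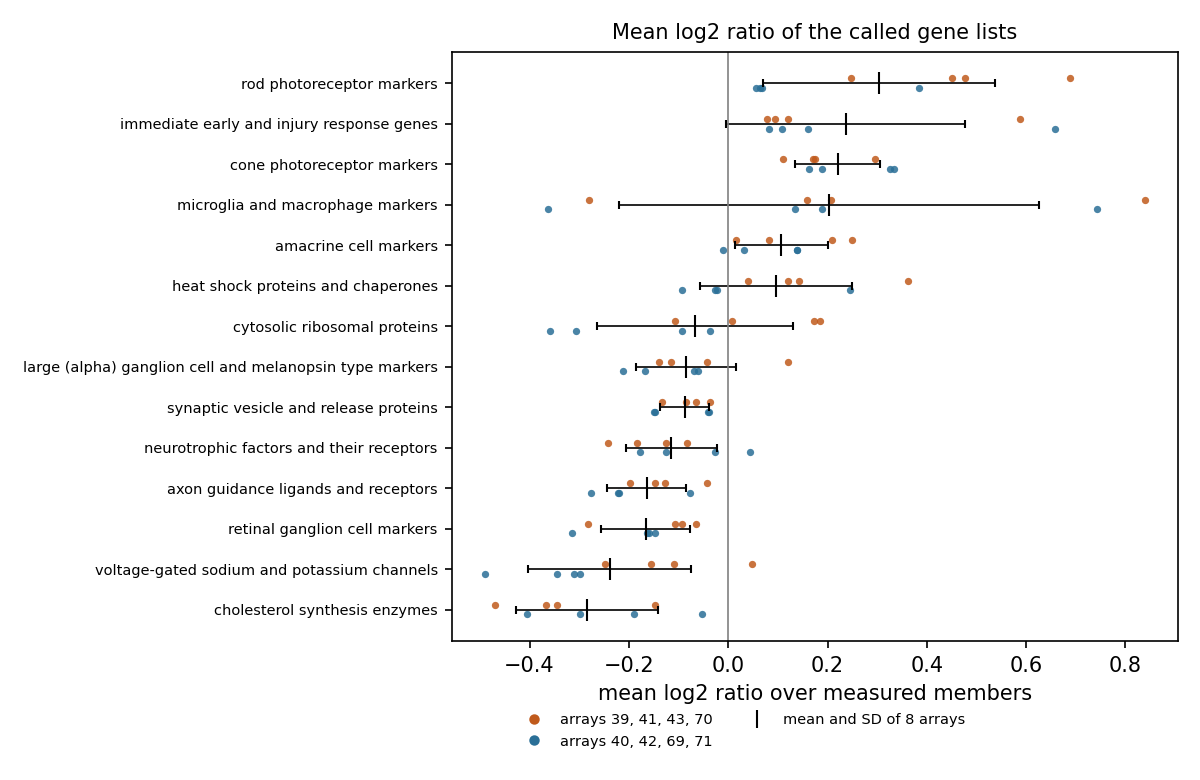
Mean log2 ratio over the measured members (horizontal axis) of the 14 called gene lists on each of the 8 arrays, coloured by set, with the mean and SD over arrays as black bars, after leaving out values at the end of the ratio scale and exact 0 values. Rod markers are highest at 0.30, cholesterol synthesis enzymes lowest at -0.28, and microglia markers spread from -0.36 to 0.84.

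The other 23 lists were not called, with camera adjusted p from 0.0529 to 0.992. Chemokines and cytokines came closest (mean 0.15 ± 0.17, adjusted p = 0.0529), and their called member, the neuronal chemokine Cx3cl1 at -0.67 ± 0.36, lay on the opposite side. Among bipolar cell markers (adjusted p = 0.0766), the transcription factor Otx2 at 0.49 ± 0.21 and the channel Trpm1 at 0.42 ± 0.16 were called. Müller glia and astrocyte markers had a mean of 0.02 ± 0.08 over 23 members (adjusted p = 0.615), with Rlbp1, a retinaldehyde-binding protein, called at 0.50 ± 0.31. Vascular markers (adjusted p = 0.615, Col4a1 at -0.25 ± 0.17 and Igfbp7 at -0.24 ± 0.37), horizontal cell markers (adjusted p = 0.646), pigment epithelium markers (adjusted p = 0.8), myelin markers (adjusted p = 0.952), red blood cell markers (adjusted p = 0.182, Hbb at -0.52 ± 0.98) and lens crystallins (adjusted p = 0.829) had no called member.

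Among receptors and channels that were not called as lists, the GABA receptor subunit Gabbr2 at -0.60 ± 0.41, the glycine receptor subunit Glrb at -0.45 ± 0.25 and the glutamate receptor subunit Gria3 at -0.41 ± 0.25 were called on the negative side, and Gabrr1 at 0.28 ± 0.09 on the positive side. The 3 probes of Gria3 had means from -0.65 to -0.06. The list adjusted p was 0.296 for GABA and glycine receptors and 0.22 for ionotropic glutamate receptors. Of calcium channel subunits (adjusted p = 0.8), Cacnb3 was called at -0.56 ± 0.27 and Cacnb2 at 0.38 ± 0.12. Apoptosis regulators (adjusted p = 0.992) held a called member on each side, Bax at -0.36 ± 0.17 and Bcl2l11 at 0.51 ± 0.28. So did antigen presentation genes (adjusted p = 0.274), with B2m at -0.37 ± 0.12 and RT1-Da at 0.41 ± 0.19. Ccnd2 at 0.34 ± 0.17 was called among cell cycle genes (adjusted p = 0.469).

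Neurofilaments, microtubule proteins and axonal motors had 0 called members and a list adjusted p of 0.496, with Stmn3 at -0.72 ± 0.88 and Stmn4 at -0.66 ± 0.80 as the largest values. Stmn3 differed between the sets of arrays (means of 0.08 and -1.52) and was called with set as a covariate (limma adjusted p = 0.00267), also with neighbouring arrays as a random block (0.0113). Over the averages of neighbouring arrays it was not called (limma adjusted p = 0.0978). No member was called among interferon-stimulated genes (adjusted p = 0.182, Gbp5 at 0.67 ± 1.06), antioxidant enzymes (0.373, Gsr at -0.38 ± 0.34), oxidative phosphorylation subunits (0.498, Atp5f1a at 0.53 ± 0.91), glycolysis enzymes (0.573, Hk2 at 0.87 ± 1.48), extracellular matrix genes (0.578), proteasome subunits (0.615, Psmd13 at 0.25 ± 0.64) or calcium-binding proteins (0.8, S100a10 at -0.41 ± 0.59). Mean, median and test differed in sign for Müller glia, myelin, calcium channels, apoptosis regulators and glycolysis enzymes. Of the 37 lists, 14 were called in all, 6 on the positive and 8 on the negative side. Over the 4 averages of neighbouring arrays camera called 13 of them. With an estimated correlation 3 were called, and 0 with the set of arrays as a covariate besides.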

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

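All tests of explanations in this part were chosen after the results were seen. A value far from the other 7 arrays was found for 2 of 93 named genes and 3 of 37 lists, where chance gives about 1 in 20. Cartpt stood at 0.0242 on array 39, with the next array at -0.72. Hk2 stood at 4.46 on array 40, with the next at 0.78. The list of large and melanopsin ganglion cell markers stood at -1.14 on array 40 and the axon guidance list at 0.25 on array 39, where Il1rapl2 and Epha3 are at the end of the ratio scale. Cell cycle genes stood at -0.16 on array 40, with the next at -0.01. Outside the named genes, 270 of 17674 probes without a single gene symbol were called when every probe was tested alone, 155 on the negative and 115 on the positive side.

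If swapped arrays had been left unturned, the biology would lie on the difference between the opposing sets of arrays. In a model with both terms, 1 of the 37 lists, lens crystallins, was called on that difference and 12 on the mean. Of the 37 lists, 26 had the same sign in both sets. These counts cannot decide on that explanation. A list is weighed by camera against the spread of all genes, which was wider on the difference (SD over probes 0.277) than on the mean (0.197). With an estimated correlation 0 lists were called on either term. A dye response belongs to a probe and less to its gene, and the correlation between 2 probes of a gene over 5514 genes was 0.0993 on the difference and 0.261 on the mean, which is consistent with dye responses left in ratios whose swapped arrays had already been turned. Values at the end of the scale were positive on arrays 39, 43 and 70 (25, 1 and 3) and negative on array 40 (44). The labels list a single dye orientation, so the assignment stays a hypothesis.

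For photoreceptor markers on the positive side and ganglion cell markers on the negative side, a dye response stays open: 3 of 3 lists (rods, cones, ganglion cells) had the same sign in both sets, but the labels give 1 dye orientation for all arrays, and the lists were picked for their mean over both sets. The 26 rod and cone markers averaged 0.29 above the 70 markers of Müller glia, vessels, horizontal cells, pigment epithelium and myelin, and 0.24 above the 140 markers of all 10 other lists but ganglion cells (1-sided permutation p = 1e-05 over genes in both, the smallest these permutations can give). The gap to microglia alone was 0.07 (permutation p = 0.135). These gaps cannot decide on a lower share of ganglion cells with all other types raised alike. Markers without signal would lie near 0 whatever the shares, and signal over background was not available. The 70 markers averaged -0.01 (SD 0.13 over genes), and 1087 olfactory receptors 0.0006 (SD 0.10 over genes). The rod and cone lists were also picked for their means, and the permutations take genes as independent. RNA of rods carried into 1 of the sorted fractions stays open, and whether sorting for the tracer removed it was not tested. The 7 abundant rod transcripts measured (Gnat1 at 0.44 ± 0.35, Sag at 0.32 ± 1.07, Pdc at 0.26 ± 0.88, Rcvrn at 0.24 ± 0.29, Rom1 at 0.12 ± 0.23, Gngt1 at -0.01 ± 0.38 and Prph2 at -0.10 ± 0.49) differed by -0.21 from the 10 other rod markers (1-sided exact permutation p = 0.0309 over genes). The first bound for this test was a p under 0.05, under which the value argued against carried-over rod RNA, and a gap above the SD of those markers (0.23) was demanded only after the p was known, because bright spots may be compressed and intensities were not analysed here. A difference between large and small cells themselves stays open and untested.

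Immediate early genes had their highest ratios on the arrays with the highest ratios of microglia markers, of which 0 were called (Ctss at 0.53 ± 0.69, C1qa at 0.29 ± 0.74 over the 8 arrays). Whether sorting for the tracer removed microglia was not tested. A line fitted over the 8 arrays takes them as independent, so its SE is too small where arrays share a biological replicate. Leaving out 1 array then keeps its partner. At a microglia mean of 0 the fitted mean of the immediate early list over the 8 arrays was 0.134 (SE 0.0488), and from 0.0894 (without array 42) to 0.155 without single arrays. It lay above 0 by more than 2 SE over all arrays, but the lowest of these values lay within 2 of the same SE, so microglial RNA as the whole cause cannot be told apart from a part of its own. Transcription during dissociation, with the inhibitor present, stays open as well. A list of genes that microglia induce during dissociation was positive on 8 of 8 arrays (mean 0.17 over 26 members, camera adjusted p = 0.00227, and 0.133 with an estimated correlation). But this came from members that the fixed lists also hold. The 10 others averaged 0.02 (SD 0.16 over genes) and moved both ways (limma camera p = 0.743, 2-sided permutation p = 0.534 over genes). A difference between large and small cells stays open and untested.

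Sign flips of single arrays were counted as a check on chance. Of 100 drawn flips, the real one included, 2 called as many as 314 genes. The highest other, 4158 genes, turned arrays 40, 42, 69 and 71 and so follows the sets, which is a structure of the arrays. With set as a covariate the real value was 918 and the highest of the other 98 flips gave 108, so 1 of 99 was as large. Both counts take the 8 arrays as independent, while the labels give 2 technical subreplicates per biological replicate, so neither share excludes chance. If neighbouring arrays are pairs, there are 8 flips and the smallest share is 0.125, too few for a share under 0.05, with a real value of 918 and 108 as the highest other.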

How the results depend on the processing

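The alternatives with the set of arrays, neighbouring title numbers, end-of-scale values and arrays 39 and 40 were chosen after the result was seen. The gene count of 314 depended on how arrays were counted as replicates. Averages over 100 drawn pairings of the 8 arrays gave a median of 0 genes, from 0 to 1440, with 0 called under every drawn pairing; over the 24 pairings across the sets the median was 639.5, from 0 to 1440, with 0 called under every one. The neighbouring pairing called 0, and with neighbouring arrays as a random block and set as a covariate limma called 439, of which 275 were among the 314. The set as a covariate alone gave 918, including all 314, set 1 alone 2883 and set 2 alone 1975, where the difference between the sets adds to the mean. Arrays 39 to 43 alone and 69 to 71 alone gave 0 each, with 1299 and 1130 genes at an unadjusted p under 0.05. The exact sign-flip test gave 0 after adjustment; its smallest possible p of 0.00781 was reached by 653 genes against 116 expected by chance over independent arrays, and 1835 genes had an unadjusted p under 0.05. Every probe tested alone gave 706 probes, the most variable probe per gene 191 genes, array weights 570 and a 2-fold limit 7. Leaving out single arrays gave 118 to 304 genes. Without arrays 39 and 40 there were 390 genes, 36.2% on the positive side against 25.8%. Lists fell from 14 to 9 with arrays 39 to 43 alone, 3 with an estimated correlation (0 with set as a covariate besides), 11 with fry, 3 with set 1 alone, 9 with set 2 alone and 9 without arrays 39 and 40, and ranged from 11 to 16 when single arrays were left out. With fry, 5 of the 14 lost the call: microglia (adjusted p = 0.344), immediate early genes (0.0653), heat shock proteins (0.175), amacrine markers (0.06) and ribosomal proteins (0.39), and bipolar markers and ionotropic glutamate receptors were called. Ribosomal proteins turned to 0.0655 with set 1 alone, and lens crystallins turned to 0.20 with set 2 alone; the difference between the sets is built into these settings, and for the other changes the cause was not tested. No named gene changed sign with its call kept, but all 54 called named genes lost the call over the averages of neighbouring arrays, 19 with the most variable probe, 13 with the title run as a covariate, 8 without arrays 39 and 40, 6 with the random block and 2 with median centring. Of the named genes not called, Stmn3, Gad2, Col4a1 and Gsr were called with set as a covariate, Stmn3 with the random block, Slc2a3 and Psmd1 without arrays 39 and 40, and Col4a1 with the most variable probe. Median centring and scaling gave 302 and 352 genes. No signal over background is in the values used, so its effect was not examined.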

Other observations

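The lists, genes and tests of this part were chosen after the data were seen. Neuropeptides and hormones lay on the negative side (mean -0.21 ± 0.11 over 39 members, camera adjusted p = 2.96e-06 over the 10 added lists, and adjusted p = 0.131 with an estimated correlation). The list was drawn up after Tac1 and Nppc had been seen, so this p tests little. Without these and Cartpt the mean was -0.14 ± 0.10 over 36 members, negative on 7 of 8 arrays (camera adjusted p = 0.000458, and adjusted p = 0.133 with an estimated correlation). Leaving them out does not make this p independent support, since the list was still chosen after the data were seen. Besides these 3, the called members were Calcb at -0.58 ± 0.27, the secretory granule proteins Chgb at -0.52 ± 0.21 and Chga at -0.46 ± 0.27, Adm at -0.52 ± 0.14 and Adcyap1, the precursor of PACAP, at -0.37 ± 0.11. The 2 probes of Chga had means of -0.86 and -0.06. Mitochondrial ribosomal proteins were negative on 8 of 8 arrays (mean -0.11 ± 0.05 over 70 members, adjusted p = 3.04e-05, and adjusted p = 0.0403 with an estimated correlation, but 0.218 with the set of arrays as a covariate besides), with 0 members called singly. Splicing factors lay on the positive side on 6 of 8 arrays, with a mean of 0.24 in set 1 and -0.02 in set 2 (mean 0.11 ± 0.18 over 32 members, adjusted p = 0.00107, and adjusted p = 0.218 with an estimated correlation).

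Lysosomal proteins (adjusted p = 0.0128, Neu1 at -0.76 ± 0.28 and Mcoln1 at -0.49 ± 0.25), ATF4 targets (adjusted p = 0.0128, Trib3 at -0.62 ± 0.20) and N-glycosylation enzymes (adjusted p = 0.0128, Mogs at -0.59 ± 0.18) lay on the negative side, each with an adjusted p = 0.133 with an estimated correlation. The list of genes that microglia induce during dissociation was on the positive side (mean 0.17 ± 0.13 over 26 members, adjusted p = 0.00227, and adjusted p = 0.133 with an estimated correlation). Folding enzymes of the endoplasmic reticulum (adjusted p = 0.135, Manf at -0.53 ± 0.13), vacuolar proton pump subunits (adjusted p = 0.907) and 1087 olfactory receptors (adjusted p = 0.262) were not called.

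A hypothesis is that arrays of neighbouring title numbers share a biological replicate. After the mean of its set was removed from each array, the correlation across 14665 genes was 0.33 for arrays 39 and 40, 0.57 for 41 and 42, 0.22 for 43 and 69, and 0.21 for 70 and 71. The highest with any other array of the opposite set was -0.03, -0.02, 0.09 and 0.01 for arrays 39, 41, 43 and 70. The mean of 0.334 ranked 1 of the 24 pairings across the sets, the next being 0.25, which leaves 4 biological replicates of 2 arrays each as a possibility. If it holds, the gene calls over 8 arrays count each replicate more than once, and the averages over pairs, which call 0 genes at an adjusted p under 0.05, may be the better guide to which genes pass. The pairing was taken up because it ranked first, so the rank cannot test it, and the labels would have to settle it.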
